A study of Homo sapiens with 8 samples.

How the data were processed

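The series holds 8 RNA-seq libraries of the human colorectal cancer cell lines RKO and SW480, 2 for each of 4 groups: RKO control, RKO with CYP1B1 overexpression, SW480 with a non-targeting hairpin (shNT) and SW480 with a hairpin against CYP1B1 (shCYP1B1). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells grew in DMEM with 10% serum at 37 °C and 5% CO2 and received lentivirus, RNA was extracted with TRIzol, and libraries were made from 1 µg of total RNA with a stranded mRNA kit. The time given for the virus treatment is marked with a unit that could not be interpreted and is not used. The hairpin series has 1 hairpin, so effects off the target cannot be separated from those of CYP1B1.

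The authors deposited a table of raw read counts per gene and a table of FPKM for the same genes and libraries. The reference was GRCh38.p13, per the submitters' processing notes; the aligner, the counting tool, the annotation and the use of strand in counting are not given in the sources used here. The deposited counts are whole numbers that sum to between 31550173 and 34921085 per library. The deposited FPKM values equal the count divided by a length per gene and by the total count of the library, and the length this implies for CYP1B1 is 5218 bp. Since the use of strand is not stated, overlapping and antisense genes cannot be told apart, and genes with near-identical copies (HSPA1A and HSPA1B, NOMO3, NPIPB2, U2AF1L5, EIF3C) are uncertain. The table held no mitochondrially encoded genes, so that list was not tested.

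All tests start from the deposited counts. Genes with too few counts were removed with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 14157 of 16829 genes. Library sizes were scaled with TMM, and negative binomial quasi-likelihood models with 1 coefficient per group were fitted over all 8 libraries in edgeR 4.0.16 under R 4.3.3, so that the 4 groups share 1 estimate of the spread on 4 residual degrees of freedom. The contrasts were overexpression minus control in RKO, shCYP1B1 minus shNT in SW480, and the difference between the lines in the CYP1B1-high minus CYP1B1-low effect. A model with cell line as a covariate gave the effect over both lines. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. The 2 lines do not share control libraries. CYP1B1 levels per library are CPM of the library total with exact Poisson intervals, and the CPM of other genes are scaled with TMM factors. Exact permutation of 2 libraries against 2 cannot give a p below 0.333, so no permutation test was run on single genes.

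Gene lists were tested with camera in limma 3.58.1 on log2 CPM with voom weights and a preset correlation of 0.01 between genes, adjusted over the 30 lists tested in each comparison; an estimated correlation and the rotation test fry were alternatives. The lists were written from textbook knowledge before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. The rule names CYP1B1 and 10 fixed genes; the 8 genes with the largest fold change each way in each line that passed the test, whose libraries did not overlap between groups and that reached 5 CPM; the 6 genes with the smallest p each way over both lines; up to 6 genes called in both lines in each sense; and up to 4 members of each list described. Some of the genes it selects are not reported here, although counts of genes include them. The choice of which lists to describe with examples was made after the list results were seen. CD99-2, an entry of a pseudoautosomal gene, was left out. Medians of lists with members at 0 in a group were recomputed with those members at a bound of 3 counts per library or left out, and the largest shift was for stromal markers in RKO, whose median fell by 0.09.

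The alternatives were RLE scaling, library size only, no filter on low counts, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma on log2 of FPKM plus 1 or plus 0.1 with and without a filter, a test against a fold change of 1.5, removal of CYP1B1, each line on its own, the replicate number as a block, and each library left out in turn. Where a group is left with 1 library, that library is assumed to vary like the other groups. GC content, gene positions and the CYP1B1 locus came from GENCODE release 29 on GRCh38, in which 16382 genes (97.3%) were found by symbol.

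The steps were tested on simulated data with known changes, drawn from the means and sizes of the real libraries over 14157 genes. Of these, 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold, in opposite directions in the 2 lines, with the same spread in all 4 groups. The real data held far more called genes, effects that differed between the lines and a more divergent overexpression pair, so the rates may not carry over. For RKO, 62.7% of genes changed by 1.5-fold, 97.0% of those changed by 2-fold and 100% of those changed by 4-fold were found, with 7 false among 180 calls. For SW480 the shares were 68.7%, 92.5% and 100%, with 17 false among 191 calls (8.90%), and for the model over both lines 86.6%, 98.5% and 100%, with 9 false among 199 calls. The simulated data for the difference between the lines held 0 changed genes, and edgeR called 0.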

Results

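Transcript levels were measured by RNA-seq in 2 human colorectal cancer cell lines, RKO, which is microsatellite unstable, and SW480, which carries a truncated APC gene. RKO cells with CYP1B1 overexpression were set against RKO control cells, and SW480 cells with a short hairpin against CYP1B1 (shCYP1B1) against SW480 cells with a non-targeting hairpin (shNT). According to its title, the series asked how knockdown or overexpression of CYP1B1 alters gene expression while these cells proliferate. Each of the 4 groups held 2 libraries, and the 8 libraries had total counts between 31550173 and 34921085. The table listed 16829 genes, of which 14157 had enough counts to be tested. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The 2 overexpression libraries differed from each other more than the libraries of any other group: 67 of 11087 genes differed by over 2-fold between them, compared with 10 between the RKO controls, 10 between the shNT libraries and 9 between the shCYP1B1 libraries. The chi-square statistic per gene was 42.7 for the overexpression pair, and 6.53, 5.64 and 4.65 for those 3 pairs.

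CYP1B1 encodes a cytochrome P450 monooxygenase that metabolises oestrogens, polycyclic aromatic hydrocarbons and arachidonic acid. The gene lies on chromosome 2 from 38066973 to 38109902 on the minus strand (GRCh38, GENCODE release 29), with 3 exons and a coding length of 1632 bp in a transcript of 5250 bp. In RKO, CYP1B1 stood at 0.697 and 0.726 CPM (counts scaled by the library total) in the control libraries and at 443 and 526 CPM in the overexpression libraries, with means of 0.712 ± 0.0202 and 484 ± 58.1 (SD, n = 2). The log2 fold change was 9.42 (SE 0.18, adjusted p = 7.93e-11, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The counts do not separate transcripts of the introduced CYP1B1 from those of the resident gene. In SW480, CYP1B1 stood at 1.43 and 2.20 CPM in the shNT libraries (50 and 76 counts) and at 0.354 and 0.290 CPM in the shCYP1B1 libraries (12 and 10 counts), a log2 fold change of -2.44 (SE 0.31, adjusted p = 6.43e-05 by the same test). The 95% Poisson intervals were 1.06 to 1.89 and 1.73 to 2.75 CPM for shNT, and 0.183 to 0.619 and 0.139 to 0.533 CPM for shCYP1B1. They cover counting error only.

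**Figure D1:**
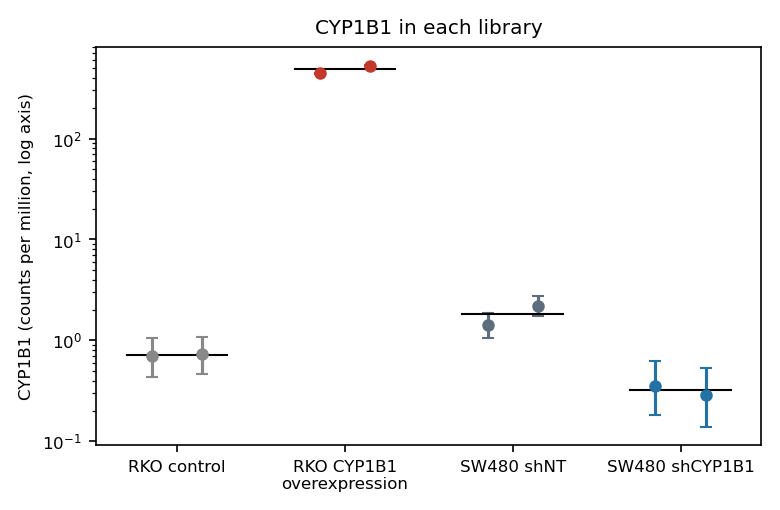
CYP1B1 in CPM of the library total (log axis) in each of the 8 libraries, with 95% Poisson intervals as bars and group means as horizontal lines. The RKO overexpression libraries stand at 443 and 526 CPM, and the other 6 libraries between 0.290 and 2.20 CPM.

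With CYP1B1 overexpression in RKO, 29 of 40 amino acid response genes and 21 of 40 immediate-early genes fell, and 22 of 44 DNA replication genes and 31 of 56 oxidative phosphorylation genes rose. These 4 lists passed with a preset correlation between genes (camera adjusted p of at most 3.89e-07) but not with an estimated correlation (adjusted p = 0.617 for each). HSPA1B, which encodes a stress-induced HSP70 chaperone, rose from 21.1 ± 0.618 to 162 ± 99.3 normalised CPM (SD, n = 2), a log2 fold change of 2.94 (SE 0.32, adjusted p = 1.39e-04, edgeR quasi-likelihood with Benjamini-Hochberg adjustment, as for all adjusted p of genes below). ESRP1, an epithelial splicing regulator, fell from 7.49 ± 0.255 to 0.244 ± 0.303 CPM (log2 fold change -4.89, SE 0.51, adjusted p = 1.19e-04). At an adjusted p threshold of 0.05, 1959 genes rose and 1948 fell out of 14157 tested, with 94 and 219 of them beyond a 2-fold change. The number of genes called was 2246 without control replicate 1, 1769 without control replicate 2, 2294 when the RKO libraries were fitted alone, and 89 when tested against a fold change of 1.5.

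Among the genes with the largest changes in RKO, the co-chaperone gene DNAJA1 rose by a log2 fold change of 1.65 (SE 0.17), HSPA1A by 2.43 (SE 0.38) and ZNF672 by 1.61 (SE 0.20). HSPE1, which encodes the small mitochondrial chaperonin, rose from 6.52 ± 1.03 to 18.5 ± 6.44 CPM (SD, n = 2). HSPA1A and HSPA1B are near-identical, so the split of reads between them is uncertain. The keratin genes KRT13 and KRT14 rose by 2.11 and 1.86, SLFN5 fell by 2.00 (SE 0.22), BEST1 by 3.32 (SE 0.51), INHBE, an activin subunit gene, by 2.67 (SE 0.60) and the cytokine gene TSLP by 2.37 (SE 0.55). NOMO3 and NPIPB2 fell by 2.45 and 2.08, and both share reads with near-identical copies. Without control replicate 2, NOMO3, NPIPB2, TSLP, INHBE and KRT14 stood at -0.31, -1.93, -2.24, -2.72 and 1.82, and neither they nor KRT13 (adjusted p = 0.0964) passed the test (adjusted p from 0.0503 to 0.440). KRT14 also lost its call without control replicate 1 (adjusted p = 0.136), without overexpression replicate 2 (0.39, adjusted p = 0.463) and without shCYP1B1 replicate 1 or 2 (adjusted p = 0.0565 and 0.0568), and INHBE without control replicate 1 (adjusted p = 0.0522). KRT13 was 3.20 without control replicate 1 and 1.18 without overexpression replicate 2, and TSLP -1.56 without the latter. Without overexpression replicate 1, ESRP1 stood at -7.80 on 1 count in replicate 2, BEST1 at -5.27, INHBE at -5.32 and TSLP at -4.50.

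Of the 40 measured genes of the ATF4 and amino acid response list, 29 fell and 0 rose in RKO (31 fell when adjusted over the list alone), with a median log2 fold change of -0.85 (camera adjusted p = 1.26e-13, and adjusted p = 0.617 with an estimated correlation). SLC7A1, the cationic amino acid transporter gene, fell by 0.95 (SE 0.06), WARS1, a tryptophan tRNA ligase gene, by 1.10 (SE 0.10), the leucine transporter gene SLC7A5 by 0.63 (SE 0.07) and the transcription factor gene ATF5 by 0.70 (SE 0.09). The estimated correlation was 0.72 for this list, and from 0.11 (MHC class I) to 0.77 (ribosomal proteins) among the lists called in RKO, against the preset 0.01. The ATF4 list's median against the controls was -0.51 in overexpression replicate 1 and -1.12 in replicate 2. Of 40 immediate-early and ERK feedback genes, 21 fell and 1 rose (23 and 2 adjusted over the list alone), with a median of -0.44, or -0.41 with a member at 0 left out (camera adjusted p = 3.89e-07, and adjusted p = 0.617 with an estimated correlation). The transcription factor genes KLF10, EGR3 and KLF6 fell by 0.72 (SE 0.07), 0.94 (SE 0.11) and 1.02 (SE 0.13), while IER5 rose by 0.97 (SE 0.10). The medians of this list were -0.37 and -0.56 in overexpression replicates 1 and 2.

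Of 44 S phase and DNA replication genes, 22 rose and 1 fell in RKO (24 and 1 adjusted over the list alone; camera adjusted p = 2.25e-08, and adjusted p = 0.617 with an estimated correlation). POLD1, the catalytic subunit gene of DNA polymerase delta, rose by 1.00 (SE 0.10), the helicase gene MCM7 by 0.81 (SE 0.10), the sliding clamp gene PCNA by 0.66 (SE 0.08) and GINS1 by 0.93 (SE 0.12). The list's medians in overexpression replicates 1 and 2 were 0.24 and 0.44. Of 51 G2/M and mitosis genes, 16 rose and 3 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.00208, and adjusted p = 0.617 with an estimated correlation). AURKB, CKS2, CCNB1 and GTSE1, all of the mitotic programme, rose by 0.62, 0.77, 0.52 and 0.77 (SE 0.08, 0.10, 0.08 and 0.12). This list did not pass without overexpression replicate 2 (camera adjusted p = 0.113).

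Nuclear-encoded oxidative phosphorylation genes moved one way in RKO: 31 of 56 rose and 0 fell (40 and 0 adjusted over the list alone; camera adjusted p = 5.40e-12, and adjusted p = 0.617 with an estimated correlation). The ATP synthase genes ATP5MC1 and ATP5MC3 rose by 0.98 (SE 0.09) and 0.84 (SE 0.07), and the cytochrome c oxidase genes COX5A and COX6B1 by 0.68 (SE 0.07) and 0.59 (SE 0.07). Of 72 cytosolic ribosomal protein genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 1.73e-07, and adjusted p = 0.617 with an estimated correlation), among them RPS14 by 0.39, RPL18 by 0.36, RPS15 by 0.33 and RPL15 by 0.32 (SE 0.06, 0.07, 0.07 and 0.06). This list did not pass without overexpression replicate 1 (camera adjusted p = 0.0577). Of 26 cholesterol biosynthesis genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 1.40e-04, and adjusted p = 0.617 with an estimated correlation). SQLE, DHCR7 and NSDHL, enzymes of the pathway, rose by 0.62, 0.66 and 0.64 (SE 0.07, 0.08 and 0.09). Medians in overexpression replicates 1 and 2 were 0.35 and 0.11 for cholesterol biosynthesis, and 0.25 and 0.05 for ribosomal proteins. They were 0.31 and 0.22 for oxidative phosphorylation, and 0.19 and 0.08 for the MHC class I list that follows. Of 22 MHC class I antigen presentation genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0297, and adjusted p = 0.617 with an estimated correlation), among them the immunoproteasome gene PSMB9 at 1.05 (SE 0.14) and the chaperone gene CALR at 0.32 (SE 0.07). This list did not pass without control replicate 2 (camera adjusted p = 0.117) or overexpression replicate 1 (camera adjusted p = 0.121), nor did CALR without control replicate 2 (adjusted p = 0.0602).

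The aryl hydrocarbon receptor (AHR) is the ligand-activated factor that drives CYP1 genes. In RKO, AHR fell by 0.55 (SE 0.12, adjusted p = 0.00701) and its target CYP1A1 fell by 1.41 (SE 0.30), from 1.84 ± 0.212 to 0.690 ± 0.165 CPM. Of 11 measured AHR target genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.41, a mean of -0.01 and a camera adjusted p of 0.0757. NFE2L2 fell by 0.60 (SE 0.10) and TIPARP by 0.41 (SE 0.07). Of 25 ferroptosis suppressors, 7 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.135). SLC7A11, the cystine transporter gene, fell by 1.57 (SE 0.20, adjusted p = 3.11e-04), while the ferritin gene FTL rose by 0.43 (SE 0.05) and HSPB1 by 0.55 (SE 0.07). GPX4, the lipid hydroperoxide reductase gene, stood at 0.22 (SE 0.08, adjusted p = 0.0620). Of 24 ferroptosis promoters, 5 rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.942), with PEBP1 and VDAC3 up by 0.67 and 0.58, and SLC38A1 and NCOA4 at -0.78 and -0.37. ACSL4 fell by 0.28 (SE 0.08, adjusted p = 0.0201), with adjusted p = 0.0690 without control replicate 1, 0.146 without control replicate 2, and a value of -0.18 without overexpression replicate 2. MYC (-0.21), CDKN1A (-0.26), FBXO10 (-0.14), AXIN2 (0.04) and MKI67 (-0.08) did not pass, with adjusted p between 0.0650 and 0.909. With DESeq2, MYC, CDKN1A and GPX4 passed (adjusted p = 0.0303, 0.0436 and 0.0342), and MYC passed with RLE scaling and with library size only (0.0454 and 0.0447), while over all 14 alternatives the largest adjusted p of MYC, CDKN1A and GPX4 were 0.228, 0.296 and 0.272. Without overexpression replicate 1, MYC, CDKN1A, FBXO10, AXIN2 and MKI67 stood at -0.34, -0.44, -0.49, 0.29 and 0.28. Without overexpression replicate 2, GPX4 stood at 0.30, MKI67 at -0.55, AXIN2 at -0.27 and FBXO10 at 0.13. AXIN2 stood at -0.02 without control replicate 1. A fit with 1 overexpression library holds no estimate of that group's own spread. MKI67 stood at 386 and 686 CPM in overexpression replicates 1 and 2, and at 581 and 549 CPM in the controls.

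Of 25 epithelial genes in RKO, 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.379): KRT8 rose by 0.72 (SE 0.07), the junction genes TJP1 and DSP fell by 0.68 and 0.61 (SE 0.09 for both). Of 30 mesenchymal genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.862), with ITGA5, CCN1 and CCN2 at -0.49, -1.01 and -1.17. THBS1 fell from 111 counts in the control libraries to 3, a ratio of 0.0259 (95% counting interval 0.00526 to 0.0777), with a fitted log2 fold change of -5.14. It stood at -8.82 without overexpression replicate 1, a value that depends on the prior count because replicate 2 had 0 counts. The other 17 lists did not pass, with camera adjusted p from 0.0698 to 0.936. Numbers that rose and fell were 7 and 2 of 28 for fatty acid synthesis, 7 and 1 of 31 for fatty acid oxidation, 1 and 3 of 21 for eicosanoid metabolism and 3 and 1 of 20 for phase I and II drug metabolism. They were 5 and 6 of 30 for p53 targets, 5 and 3 of 27 for Wnt targets, 5 and 5 of 37 for the interferon response, 3 and 6 of 29 for NF-kB, and 5 and 10 of 29 for apoptosis regulators. They were 9 and 8 of 26 for the unfolded protein response, 10 and 4 of 31 for NRF2 targets, 10 and 6 of 40 for hypoxia, 9 and 6 of 39 for ribosome biogenesis and 6 and 3 of 30 for autophagy. They were 2 and 1 of 12 for replication-dependent histones, 0 and 0 of 10 for intestinal differentiation, and 1 and 0 of 16 for stromal, endothelial and immune cell markers. Adjusted over the list alone, the numbers differed for apoptosis (7 and 10), the unfolded protein response (10 and 8), NRF2 (10 and 6), hypoxia (11 and 6), ribosome biogenesis (12 and 8), autophagy (9 and 5) and stromal markers (0 and 0). Median, mean and camera direction differed in sign for fatty acid synthesis, p53 targets, intestinal differentiation, interferon, unfolded protein response, NRF2 and apoptosis.

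With CYP1B1 knockdown in SW480, 34 of 44 DNA replication genes fell, and 19 of 26 cholesterol biosynthesis genes and 17 of 30 mesenchymal genes rose. These 3 lists passed with a preset correlation between genes (camera adjusted p of at most 6.49e-05) but not with an estimated correlation (adjusted p = 0.501 for each). The chemokine gene CXCL1 fell from 39.6 ± 2.87 to 2.45 ± 1.26 CPM (SD, n = 2), a log2 fold change of -4.01 (SE 0.29, adjusted p = 1.35e-06), and the epithelial adhesion gene EPCAM from 131 ± 0.336 to 22.9 ± 0.576 CPM (-2.52, SE 0.09, adjusted p = 3.45e-08). INSIG1, which retains sterol regulators in the endoplasmic reticulum, rose from 17.0 ± 0.690 to 95.4 ± 1.66 CPM (2.49, SE 0.14, adjusted p = 3.09e-07). In all, 3588 genes rose and 3579 fell out of 14157 tested, with 1009 and 904 of them beyond a 2-fold change. Tested against a fold change of 1.5, 1994 genes passed. This comparison rests on CYP1B1 levels near 2 CPM or below in every library.

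Of the genes with the largest rises in SW480, HSD11B1, whose enzyme regenerates active cortisol from cortisone, went from 0.116 ± 0.164 to 22.7 ± 0.450 CPM (7.57, SE 0.51). Without shNT replicate 2 it stood at 12.58, a fitted value that depends on the prior count because the remaining shNT library had 0 counts. SLA, a Src-like adaptor gene, rose by 5.83 (SE 0.24), the apelin receptor gene APLNR by 5.69 (SE 0.39), the chemerin receptor gene CMKLR1 by 5.60 (SE 0.64) and PRR9 by 5.16 (SE 0.13). TMEM132C, the sphingomyelinase gene SMPD3 and the glutamate receptor gene GRIA1 rose by 4.87, 4.84 and 4.81 (SE 0.46, 0.39 and 0.41). MYT1, a zinc finger transcription factor gene, fell by 5.23 (SE 0.69), CXCL2 by 4.01 (SE 0.48), CXCL3 by 3.93 (SE 0.34) and CXCL8 by 3.38 (SE 0.39). The interferon-inducible gene SAMD9 fell by 3.56 (SE 0.22) and PLPPR4 by 3.53 (SE 0.42). U2AF1L5, a near-identical copy of U2AF1, fell by 4.32 (SE 1.06), but stood at -0.53 (adjusted p = 0.386) without shNT replicate 2 and at adjusted p = 0.0610 and 0.0560 without shCYP1B1 replicates 1 and 2.

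Of 44 S phase and DNA replication genes, 34 fell and 2 rose in SW480 (34 and 2 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 8.90e-08, and adjusted p = 0.501 with an estimated correlation). TYMS, the thymidylate synthase gene, fell by 1.15 (SE 0.08), GINS2 by 1.23 (SE 0.10) and PCNA by 1.05 (SE 0.08). Of 39 ribosome biogenesis and MYC target genes, 17 fell and 6 rose (17 and 6 adjusted over the list alone; camera adjusted p = 0.0383, and adjusted p = 0.501 with an estimated correlation). GRWD1, NOP56, IPO4 and the RNA polymerase I gene POLR1A fell by 1.28, 1.07, 1.17 and 1.22 (SE 0.08, 0.07, 0.11 and 0.12). MYC rose by 0.35 (SE 0.08, adjusted p = 0.00297) and the cyclin-dependent kinase inhibitor gene CDKN1A by 0.64 (SE 0.10, adjusted p = 3.10e-04). MKI67 fell by 0.57 (SE 0.19, adjusted p = 0.0252) and the Wnt target AXIN2 by 0.33 (SE 0.11, adjusted p = 0.0307). Both lost their call without each of the 4 SW480 libraries and each RKO control, with adjusted p from 0.0508 to 0.180 for MKI67 and from 0.0584 to 0.220 for AXIN2, as did MKI67 with DESeq2 (adjusted p = 0.126) and AXIN2 with RLE scaling (adjusted p = 0.0511). The ribosome biogenesis list did not pass without shNT replicate 2 (camera adjusted p = 0.0622).

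Of 30 mesenchymal genes, 17 rose and 3 fell in SW480 (17 and 3 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 6.49e-05, and adjusted p = 0.501 with an estimated correlation). The collagen cross-linking gene LOXL2 rose by 1.85 (SE 0.08), and the matrix genes SPARC and TGFBI by 1.69 (SE 0.09) and 1.19 (SE 0.07). Of 25 epithelial genes, 14 fell and 6 rose (15 and 7 adjusted over the list alone), with a median of -0.86 and a camera adjusted p of 0.0585. LAD1, ST14 and the desmosomal gene PKP3 fell by 2.26, 1.21 and 0.98 (SE 0.16, 0.08 and 0.08). Of 29 NF-kB and inflammatory response genes, 17 fell and 4 rose (18 and 5 adjusted over the list alone; camera adjusted p = 0.00113, and adjusted p = 0.501 with an estimated correlation). The monocyte chemokine gene CCL2 fell by 2.59 (SE 0.19) and TNFAIP2 by 1.49 (SE 0.08), beside CXCL1 and CXCL3. Of 40 immediate-early and ERK feedback genes, 18 rose and 4 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.0330, and adjusted p = 0.587 with an estimated correlation). NR4A1, EGR3, JUN and SPRED2 rose by 1.63, 1.42, 0.91 and 0.81 (SE 0.12, 0.10, 0.09 and 0.07).

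Of 26 cholesterol biosynthesis genes, 19 rose and 1 fell in SW480 (19 and 1 adjusted over the list alone; camera adjusted p = 3.59e-05, and adjusted p = 0.501 with an estimated correlation). Beside INSIG1, MSMO1 rose by 2.14 (SE 0.17) and SQLE by 1.15 (SE 0.07). Of 20 phase I and II drug metabolism genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.0416, and adjusted p = 0.501 with an estimated correlation). CYP3A5 rose by 2.36 (SE 0.19), the sulfotransferase gene SULT1A1 by 1.08 (SE 0.15) and GSTO1 by 0.95 (SE 0.09), and the efflux pump gene ABCB1 fell by 0.78 (SE 0.09). Of 40 hypoxia and glycolysis genes, 18 rose and 4 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.0466, and adjusted p = 0.587 with an estimated correlation), with ANKZF1, MXI1, ENO2 and ERO1A up by 1.21, 1.11, 1.06 and 0.66 (SE 0.09, 0.11, 0.08 and 0.07). Without shNT replicate 2, neither drug metabolism (camera adjusted p = 0.0622) nor hypoxia (0.0600) passed, and hypoxia did not without shCYP1B1 replicate 1 (camera adjusted p = 0.0574). Drug metabolism also stood at a camera adjusted p of 0.0565 with no filter on low counts.

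AHR fell by 0.31 (SE 0.11, adjusted p = 0.0343) in SW480, and CYP1A1 stood at -0.12 (SE 0.23, adjusted p = 0.690). AHR lost its call without any 1 of the 4 SW480 libraries (adjusted p from 0.0806 to 0.188) and with DESeq2 (adjusted p = 0.0564). Of 11 AHR target genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.209). The AHR repressor gene AHRR fell by 1.22 (SE 0.19) and SLC7A5 by 0.85 (SE 0.07), while ARNT, the partner of AHR, and IL1R2 rose by 0.31 (SE 0.09) and 2.03 (SE 0.56). Those 2 rises did not pass without shNT replicate 2 (adjusted p = 0.0869 and 0.0790) or shCYP1B1 replicate 2 (adjusted p = 0.0672 and 0.0823). Of 25 ferroptosis suppressors, 12 rose and 6 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.331). GPX4 rose by 0.69 (SE 0.08, adjusted p = 2.81e-05) and HSPB1 by 0.70 (SE 0.07), whereas SLC7A11 fell by 2.09 (SE 0.23, adjusted p = 2.25e-05) and FANCD2 by 1.33 (SE 0.11). Of 24 ferroptosis promoters, 4 rose and 11 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.161). The transferrin receptor gene TFRC fell by 2.03 (SE 0.12), FADS1 by 0.86 (SE 0.08) and SLC38A1 by 0.85 (SE 0.06), and the polyamine enzyme gene SAT1 rose by 2.21 (SE 0.18). FBXO10 (0.23, SE 0.17, adjusted p = 0.299) and ACSL4 (0.18, SE 0.08, adjusted p = 0.0751) did not pass. ACSL4 passed without overexpression replicate 1 or 2 of RKO (adjusted p = 0.00219 and 0.00220), and with RLE scaling and DESeq2 (0.0411 and 0.0376), with adjusted p up to 0.230 over its 14 alternatives.

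The other 18 lists did not pass in SW480, with camera adjusted p from 0.0813 to 0.897. Numbers that rose and fell were 9 and 16 of 51 for G2/M, 9 and 6 of 30 for p53 targets, 7 and 9 of 27 for Wnt targets, 1 and 5 of 10 for intestinal differentiation, 6 and 11 of 37 for interferon and 3 and 5 of 22 for MHC class I. They were 7 and 14 of 26 for the unfolded protein response, 7 and 11 of 40 for ATF4, 16 and 8 of 31 for NRF2, 3 and 15 of 56 for oxidative phosphorylation and 14 and 2 of 72 for ribosomal proteins. They were 7 and 3 of 21 for eicosanoids, 8 and 7 of 28 for fatty acid synthesis, 7 and 5 of 31 for fatty acid oxidation, 10 and 6 of 29 for apoptosis and 8 and 9 of 30 for autophagy. They were 2 and 2 of 12 for replication-dependent histones and 4 and 0 of 16 for stromal, endothelial and immune cell markers. Adjusted over the list alone, the numbers differed for the unfolded protein response (8 and 14), ATF4 (7 and 10), oxidative phosphorylation (3 and 14), ribosomal proteins (10 and 2) and stromal markers (2 and 0). Median, mean and camera direction differed in sign for fatty acid synthesis and fatty acid oxidation.

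**Figure D2:**
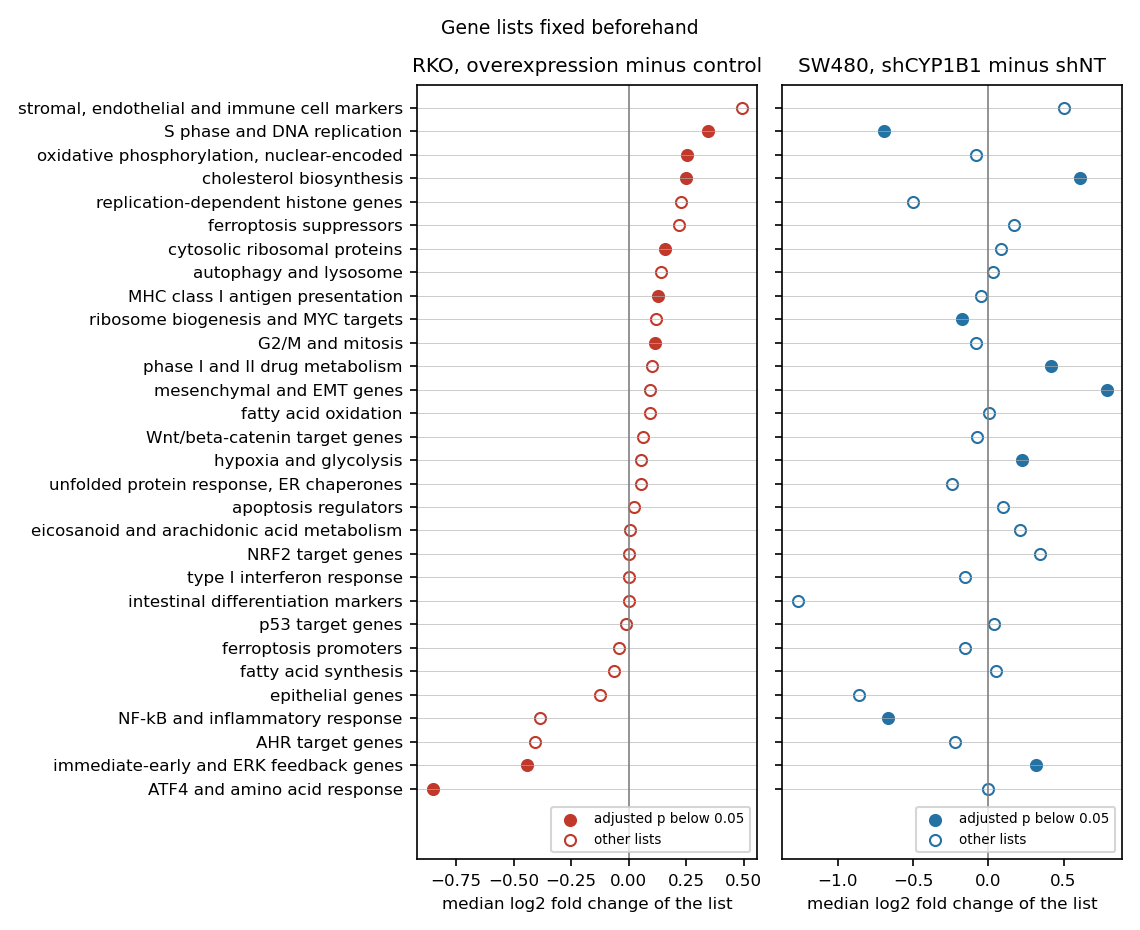
Median log2 fold change of the measured genes of each of the 30 tested lists (dots) in RKO and in SW480, filled where the camera adjusted p was below 0.05 and open otherwise. The median of S phase genes was 0.34 in RKO and -0.69 in SW480, and that of the ATF4 list was -0.85 in RKO.

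**Figure D3:**
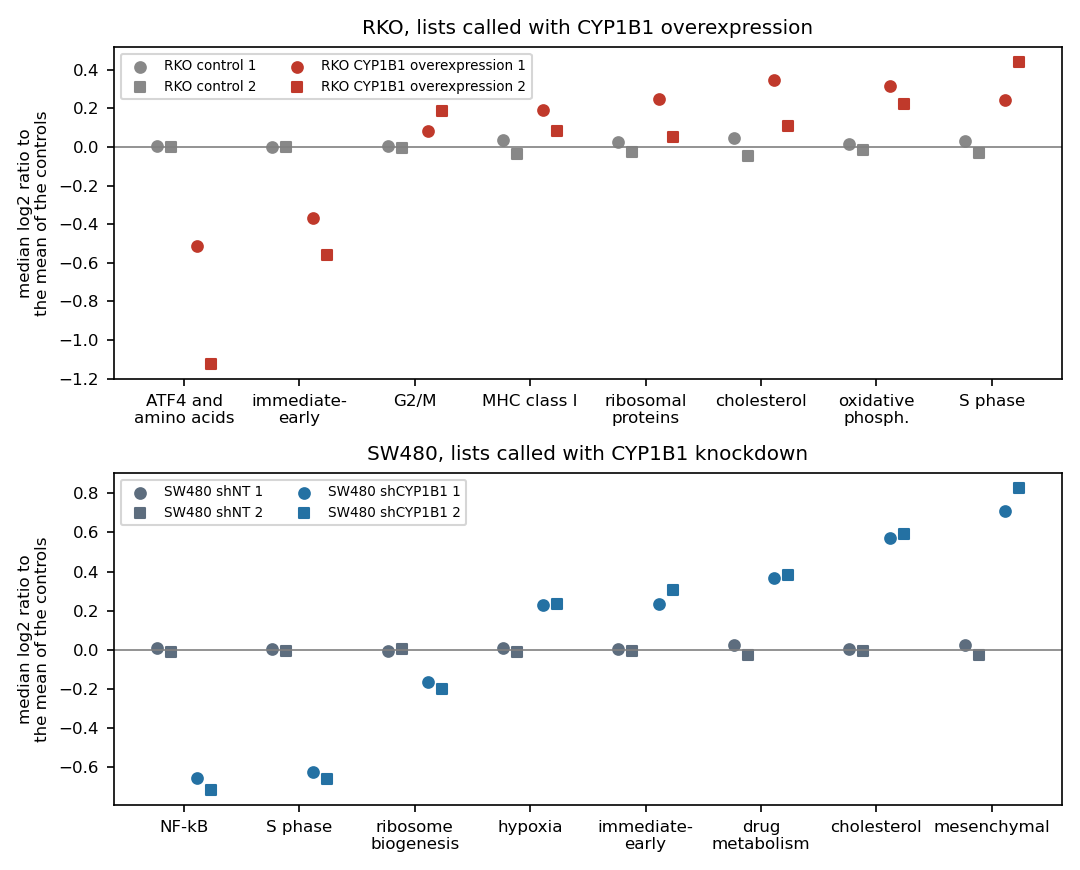
Median log2 ratio of each library to the mean of its line's control libraries, for the lists with a camera adjusted p below 0.05 in RKO and in SW480, with circles for replicate 1 and squares for replicate 2. The ATF4 median was -0.51 and -1.12 in the overexpression libraries, and the S phase median -0.62 and -0.66 in the shCYP1B1 libraries.

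A single model over both lines asked which genes followed CYP1B1, with RKO overexpression and SW480 shNT as the CYP1B1-high libraries and RKO control and SW480 shCYP1B1 as the CYP1B1-low ones (4 against 4, cell line as a covariate). The CYP1B1-high libraries were unlike, at 443 and 526 CPM in RKO overexpression and 1.43 and 2.20 CPM in shNT. The RKO controls, counted as low, stood at 0.697 and 0.726 CPM. The single coefficient thus covers a far larger change in RKO than in SW480. SLC25A10, a mitochondrial dicarboxylate carrier gene, was higher with CYP1B1 by a log2 fold change of 0.96 (SE 0.09, adjusted p = 0.00346), going from 44.9 to 82.0 CPM in RKO and standing at 63.3 with shNT and 30.4 with shCYP1B1. The RNA helicase gene DDX39A was higher by 1.06 (SE 0.10) and IGF2BP2, an mRNA-binding protein gene, was lower, at -0.81 (SE 0.07). In all, 546 genes were higher and 594 lower with CYP1B1. Others with the smallest p lay below 1 CPM in all RKO libraries, so their values rest on SW480: ST14 (1.18, SE 0.10), PLEKHB1 (1.60, SE 0.16), FOXQ1 (0.93, SE 0.10) and PTPRZ1 (3.11, SE 0.32) were higher. APLNR (-5.64, SE 0.42), SLA (-5.70, SE 0.44), IGFBP7 (-2.79, SE 0.21), SLC7A7 (-2.06, SE 0.16) and EDN3 (-2.03, SE 0.17) were lower. CYP1B1 itself was higher by 8.20 (SE 1.21, adjusted p = 0.0115), and CDKN1A was lower, at -0.45 (SE 0.11, adjusted p = 0.0461). Those called with opposite signs in both single-line comparisons as well numbered 804 (427 higher, 377 lower). Genes called with opposite signs in the single-line comparisons numbered 933 in all, against 989 expected from independent calls. They were thus not in excess. The same model called 2332 genes when both control groups were set against both manipulated groups.

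The values of AHR (-0.11), CYP1A1 (-0.56), ACSL4 (-0.23), FBXO10 (-0.19), GPX4 (-0.24), SLC7A11 (0.19), MYC (-0.28), AXIN2 (0.19) and MKI67 (0.25) over both lines did not pass, with adjusted p from 0.0560 to 0.893. Without overexpression replicate 1, MYC, AXIN2 and MKI67 stood at -0.34, 0.32 and 0.45, in a fit with no spread between overexpression libraries. Without overexpression replicate 2, AHR stood at 0.03. ACSL4 and MYC passed with DESeq2 (adjusted p = 0.00643 and 0.00369) and MYC with RLE scaling (0.0476), while the largest adjusted p over 14 alternatives were 0.276 and 0.192. SLC7A11 stood at -0.12 without shNT replicate 2, and at -0.49 and -0.41 without shCYP1B1 replicates 1 and 2. Without shNT replicate 1, CYP1B1 and PTPRZ1 (both adjusted p = 0.0538) and PLEKHB1 and FOXQ1 (both adjusted p = 0.0525) did not pass, and CDKN1A did not without any 1 of the 7 libraries other than overexpression replicate 1 (adjusted p from 0.0617 to 0.160), nor with no filter on low counts (adjusted p = 0.0509). The count of 1140 genes fell to 623 and 613 without RKO control replicates 1 and 2, 17 and 137 without shNT replicates 1 and 2, and 93 and 71 without shCYP1B1 replicates 1 and 2, and was 1953 without overexpression replicate 1 and 2727 with DESeq2. The share of calls that were higher was 47.9%, against 60.4%, 58.6% and 61.2% with limma on the 3 versions of log2 FPKM.

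Whether overexpression in RKO and knockdown in SW480 moved the same genes in opposite ways was tested on the genes called in both. IGF2BP2, the TGF-beta signalling gene SMAD3 and the kinase gene ABL2 fell in RKO by 0.84, 0.81 and 0.82 (SE 0.07 for each) and rose in SW480 by 0.78, 0.78 and 0.75 (SE 0.07, 0.07 and 0.08). SH3D19 fell by 0.88 and rose by 0.56 (SE 0.08 for both), and SLC25A10 rose by 0.87 and fell by 1.06 (SE 0.09 for both). Other genes moved the same way in both manipulated lines: the transcription factor gene RUNX1 fell by 1.18 in RKO and 0.60 in SW480, TRIM25 by 1.18 and 0.77, and CLCN3 by 0.81 and 0.59. NIBAN2 rose by 0.86 and 0.84, the actin-bundling gene FSCN1 by 1.36 and 1.13, and the membrane protease gene MMP15 by 1.41 and 1.56. Of 2222 genes called in both comparisons, 1289 moved the same way and 933 opposite ways, against 989 expected for each from independent calls. Same-way moves made up 58.0% (odds ratio 1.91, two-sided Fisher's exact test p = 3.75e-14 across genes, which are not independent replicates). The fold changes correlated weakly across genes (Pearson 0.0594, Spearman 0.0726). Without overexpression replicate 1, 1979 genes moved the same way and 1930 opposite ways (50.6%, Fisher's exact test p = 0.462). Without overexpression replicate 2 the numbers were 1986 and 1251, without RKO control replicates 1 and 2 they were 737 and 488, and 589 and 411, without shNT replicates 1 and 2 870 and 525, and 797 and 578, and without shCYP1B1 replicates 1 and 2 834 and 564, and 842 and 556.

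**Figure D4:**
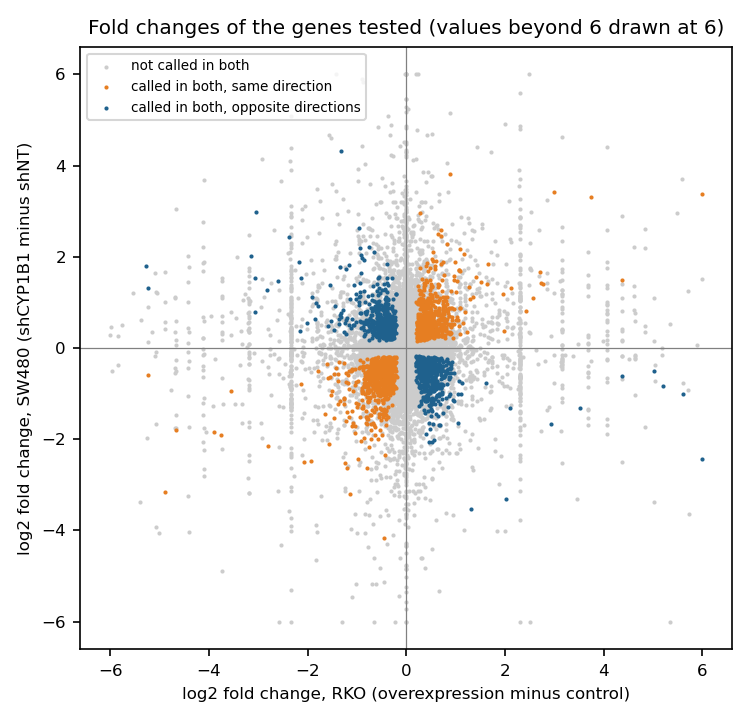
Log2 fold change of each tested gene in RKO (overexpression minus control, horizontal axis) against SW480 (shCYP1B1 minus shNT, vertical axis), with values beyond the axis limit drawn at it. Orange points are the 1289 genes called in both comparisons that moved the same way, and blue points the 933 that moved opposite ways.

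The difference between the lines in the effect of CYP1B1 (high minus low) was tested for each gene in the same model. RKO had only overexpression and SW480 only knockdown, so line, kind of manipulation and size of the CYP1B1 change cannot be told apart. A gene that moved the same way in both manipulated lines also counts as a difference here. S phase gene PCNA, which rose with overexpression and fell with knockdown, differed between the lines by -0.40 (adjusted p = 0.0171), and did not pass without RKO control replicate 1 (adjusted p = 0.0810), shNT replicate 1 or 2 (0.0698 and 0.0720) or shCYP1B1 replicate 2 (0.132). SLC7A11, which fell in both manipulated lines, differed by -3.67 (adjusted p = 7.39e-06), and SQLE, which rose in both, by 1.77. The effect was more positive in RKO than in SW480 for 2966 genes and more negative for 3062, and 1961 genes differed when tested against a fold change of 1.5. IGF2BP2 (-0.06), SMAD3 (-0.04) and ABL2 (-0.07) did not pass this test, and stood at 0.024, 0.021 and 0.0093 without RKO control replicate 2, shNT replicate 2 and RKO control replicate 2, in that order.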

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

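Tests chosen after the result was seen were those of overexpression replicate 1, of CYP1B1 acting in the same sense in both lines, of normalization, of copy number behind most SW480 changes, and of length and GC as the whole of the replicate difference.

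In the difference between the lines, the line cannot be told apart from the kind of manipulation and the size of the CYP1B1 change. The effect of CYP1B1 (high minus low) differed between the lines for 6028 genes by the edgeR test of the difference, and for 102 of the 145 named genes (adjusted p from 1.38e-06 to 0.0487). Many of these were named for large changes in 1 line or for moving the same way in both manipulated lines, so their share was largely set by that choice. Most are grouped by a fixed list that holds them, and no list was tested for the difference. The effect was more positive in RKO by a log2 difference of 6.98 for CYP1B1 itself. HSPA1A, HSPA1B, HSPE1, DNAJA1 and HSPB1 differed by 3.24, 3.21, 1.35, 1.35 and 1.25. Cholesterol pathway genes differed by 3.13 (INSIG1), 2.41 (MSMO1), 1.77 (SQLE), 0.97 (NSDHL) and 0.93 (DHCR7). Mesenchymal genes differed by 2.78 (SPARC), 2.55 (LOXL2), 1.10 (TGFBI) and 0.77 (ITGA5). MMP15, FSCN1 and NIBAN2, named for rising in both manipulated lines, differed by 2.97, 2.48 and 1.69. Replication and mitosis genes differed by 1.17 (CKS2), 1.10 (POLD1), 0.88 (AURKB) and 0.86 (GINS1). Respiratory and ribosomal protein genes differed by 1.11 (ATP5MC1), 0.56 (COX6B1), 0.42 (COX5A), 0.53 (RPL18), 0.36 (RPL15), 0.36 (RPS15) and 0.34 (RPS14). Immediate-early genes differed by 1.33 (NR4A1), 0.84 (IER5), 0.50 (JUN) and 0.43 (SPRED2), and hypoxia genes by 1.45 (ANKZF1), 1.32 (ENO2), 0.70 (MXI1) and 0.63 (ERO1A). Drug metabolism and ferroptosis genes differed by 1.37 (GSTO1), 0.92 (SULT1A1), 1.45 (SAT1), 0.91 (GPX4), 0.62 (FTL) and 0.44 (PEBP1), KRT8 by 0.98 and PSMB9 by 0.87. SPARC, LOXL2 and TGFBI lay below 2 CPM in every RKO library.

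The effect was more negative in RKO for amino acid response genes, by -3.67 (SLC7A11), -1.58 (WARS1), -1.49 (SLC7A5), -1.40 (SLC7A1) and -1.15 (ATF5). AHR differed by -0.87, CYP1A1 by -1.53, TIPARP by -0.63 and NFE2L2 by -0.55. Epithelial genes differed by -8.06 (ESRP1), -2.52 (EPCAM), -1.01 (DSP), -0.89 (TJP1) and -0.88 (PKP3). S phase genes differed by -0.77 (TYMS) and -0.65 (GINS2), and ribosome biogenesis genes by -1.19 (POLR1A), -1.02 (IPO4), -1.01 (GRWD1) and -0.96 (NOP56). Inflammatory and interferon genes differed by -3.90 (CXCL3), -0.99 (TNFAIP2) and -3.52 (SAMD9), and KLF6 and KLF10 by -1.20 and -1.12. Ferroptosis genes differed by -1.96 (FADS1), -1.63 (SLC38A1), -1.47 (TFRC), -1.41 (FANCD2) and -0.58 (NCOA4). BEST1, SLFN5 and CCN2 differed by -4.54, -1.45 and -1.70, and TRIM25, RUNX1 and CLCN3, named for falling in both manipulated lines, by -1.95, -1.78 and -1.40. CXCL3 and FADS1 lay below 1 CPM, and EPCAM and CYP1A1 below 2 CPM, in every RKO library.

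Of the 102 genes, 87 kept their call and direction under all alternatives tried for them that gave a value, and 15 lost their call under at least 1. Limma on log2 FPKM, the test against a fold change of 1.5 and removal of CYP1B1 were not tried for single genes. Without RKO control replicates 1 and 2 and without each SW480 library, CDKN1A (0.38), INHBE (-2.81) and SH3D19 (-0.32) lost it, with adjusted p from 0.0667 to 0.158, 0.0560 to 0.0701 and 0.0691 to 0.125. KRT14 (2.03) and TAP1 (0.33) lost it without any library but overexpression replicate 1 (adjusted p from 0.0687 to 0.328 and 0.0590 to 0.165), and CYP3A5 (5.51) without any but the shNT libraries (0.0647 to 0.0968). ZNF672 (0.85) lost it without either RKO control, shNT replicate 2 and either shCYP1B1 library (0.0687 to 0.163), and NOMO3 (-2.81) without RKO control replicate 2 and each SW480 library (0.0600 to 0.106). AHRR (-0.94) lost it without RKO control replicate 1, overexpression replicate 1 and each SW480 library (0.0503 to 0.181), and PCNA (-0.40) without RKO control replicate 1, either shNT library and shCYP1B1 replicate 2 (0.0698 to 0.132). GTSE1 (0.56) lost it without RKO control replicate 2, and EGR3 (0.48) without RKO control replicate 1, and both without shNT replicate 2 and either shCYP1B1 library (0.0645 to 0.111 and 0.0544 to 0.0799). MCM7 (0.53) lost it without RKO control replicate 2 or shNT replicate 2 (0.0543 and 0.0520), ATP5MC3 (0.38) without shNT replicate 2 or shCYP1B1 replicate 1 (0.0555 and 0.0501), and PRR9 (6.04) without overexpression replicate 2 (0.0582). With DESeq2, INHBE, ZNF672, NOMO3 and SH3D19 also lost it (adjusted p = 0.111, 0.0942, 0.0714 and 0.0701). With library size only CDKN1A, KRT14 and TAP1 did (0.0899, 0.0566 and 0.0911), and with no filter on low counts KRT14, SH3D19 and TAP1 (0.0513, 0.0537 and 0.0527). Values that moved by over 1.5 times were CDKN1A at 0.20, INHBE at -5.46 and THBS1 (-4.79) at -8.46 without overexpression replicate 1, and KRT14 at 0.55, ZNF672 at 0.44, GTSE1 at 0.37 and CXCL8 (-4.17) at -6.39 without replicate 2. NOMO3 stood at -0.65 without RKO control replicate 2, NPIPB2 (-4.58) at -8.32 without shCYP1B1 replicate 2 and U2AF1L5 (-6.85) at -3.05 without shNT replicate 2. PRR9, CYP3A5 and CXCL8 lay below 1 CPM in every RKO library, so their values depend on the prior count. So do those of THBS1 without overexpression replicate 1 and NPIPB2 without shCYP1B1 replicate 2, as the library left in the group had 0 counts. AHRR and THBS1 lay below 2 CPM in every RKO library, and NPIPB2 below 1 CPM in every SW480 library.

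Genes called in both comparisons moved the same way in 58.0% of cases, although CYP1B1 was raised in 1 line and lowered in the other. If CYP1B1 acted in the same sense in both lines, most would move opposite ways; 42.0% did, but 49.4% did without overexpression replicate 1, so this test leaves the question open. The same-way share was 50.6% without overexpression replicate 1 and no lower than 58.0% without any other library, so the excess may rest on that library. With a smooth trend on gene length and GC content removed in each library, 53.1% of 2036 genes moved the same way (two-sided Fisher's exact test p = 0.0187), a value between the bounds set beforehand for and against such trends. A response common to both manipulated cultures stays open.

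In SW480, 7167 of 14157 genes passed the test although CYP1B1 was near 2 CPM or below in every library. Scaling by library size only gave 7152. The TMM factors of the SW480 libraries lay between 0.965 and 0.998, so this change of scaling could hardly alter the count. It does not decide on normalization, since only scalings by 1 factor per library were tried. Removal of length and GC trends lowered the share of genes with a large fold change by 1.47% of its value (from 42.2% to 41.6%), which argues against these trends as the source. Runs of 41 neighbouring genes with a shifted median held 6.53% of all genes and 7.40% of those called, so copy number shifts of that length and size do not account for most changes. The share of all genes was 2.72% after gene order was shuffled and 3.94% in the RKO comparison, which had no shuffled level of its own. Chromosome 19 held the most genes in such runs (176), and its median over all its genes was 0.12 in SW480 and 0.11 in RKO. That shift was thus not particular to SW480. Copy number differences between the SW480 cultures could still contribute in some regions. Effects of the hairpin off its target, differences between cultures and an effect of CYP1B1 itself stay open, since there was 1 hairpin.

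The overexpression libraries differed from each other more than the libraries of any other group, with an SD of the log2 difference of 0.291 across genes. The difference correlated with GC content at 0.0264 (Spearman, across genes), which argues against a GC trend. With length and GC trends removed the SD was 0.276, while that of the most divergent other pair was 0.165 before removal, which argues against these trends as the whole of it. The correlation was 0.303 with gene length (0.255 for the shNT pair) and 0.294 with the overexpression effect, both within 2 bootstrap SEs (0.00866 and 0.00973) of the bound set beforehand, a margin added after the values were seen. A length trend, and a stronger response in replicate 2, which held more CYP1B1, therefore both stay open and could each contribute.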

How the results depend on the processing

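The limit of 5 CPM in every group and the count of genes also called in each line were chosen after the result was seen; the other alternatives were chosen before. Of 4391 values of 315 gene results under 14 alternatives, 4199 kept their direction and side of the threshold, 158 fell short of it, 22 came past it and 12 reversed. Limma on log2 FPKM, the test against a fold change of 1.5, removal of CYP1B1 and each line on its own were not among those 14. Single genes were thus not tried in RKO alone, where the count of called genes fell from 3907 to 2294. Many of the genes were also named for large changes or small p, so these shares do not carry over to all genes. With RLE scaling, library size only, no filter, 1 CPM in 4 libraries, DESeq2, and limma on log2 FPKM with its 3 settings, counts in RKO were 3201 to 4078, in SW480 6692 to 7418 and for the difference between the lines 5835 to 6718. Against a fold change of 1.5 they were 89 in RKO, 1994 in SW480, 37 over both lines and 1961 for the difference, a stricter hypothesis by construction. The RKO libraries alone gave 2294 and the SW480 libraries alone 9071, each with 2 residual degrees of freedom in place of 4. Fewer degrees of freedom alone would not raise the SW480 count. The SW480 fit leaves out the overexpression pair, whose chi-square per gene was 42.7, against 5.64 for shNT and 4.65 for shCYP1B1. The spread shared by all groups may thus be too large for SW480 and too small for RKO. Over both lines, DESeq2 gave 2727 and limma on unfiltered log2 of FPKM plus 1 gave 626, and the cause was not tested; RLE scaling, library size only, both filters and limma on filtered log2 FPKM gave 894 to 1155. With replicate number as a block, edgeR called 0 genes over both lines (2571 at an unadjusted p below 0.05, smallest adjusted p = 0.0948), and 2727 with DESeq2 without the block, but 3653 in RKO, 6891 in SW480 and 5770 for the difference; deviations at the same number correlated at -0.0688 and -0.0113 across genes, so the numbers do not pair libraries. With that block, CYP1B1 and every other gene named as called over both lines lost its call (adjusted p from 0.0948 to 0.176), as did SH3D19 and TAP1 for the difference (0.0654 and 0.0638), and MYC passed in RKO (0.0490); no other call of a named gene changed. Lists called fell from 8 to 0 in each line with an estimated correlation (smallest adjusted p = 0.617 and 0.501; 1 list in RKO and 2 in SW480 at an unadjusted p below 0.05), while fry, which compares a list with no other genes, called 4 and 21. Leaving out 1 library gave 1769 (control replicate 2) to 5621 (overexpression replicate 1) genes in RKO, 5132 (shNT replicate 2) to 8743 (overexpression replicate 1) in SW480, 17 (shNT replicate 1) to 1953 (overexpression replicate 1) over both lines and 4600 to 7146 for the difference. It gave a same-way share of 50.6% to 62.4%, 589 to 1986 genes moving the same way and 411 to 1930 opposite ways, 6 to 9 lists in RKO and 5 (shNT replicate 2) to 9 in SW480. With at least 5 CPM in every group, 56.9% moved the same way (1148 and 869) and 848 genes followed CYP1B1 over both lines. Reversed in RKO were FBXO10 (from -0.49 to 0.13 over the libraries left out), at 0.13 without overexpression replicate 2, AXIN2 (-0.27 to 0.29), at -0.27 without overexpression replicate 2 and -0.021 without control replicate 1, and MKI67 (-0.55 to 0.28), at 0.28 without overexpression replicate 1. Over both lines, AHR (-0.22 to 0.034) stood at 0.034 without overexpression replicate 2 and SLC7A11 (-0.49 to 0.92) at -0.12, -0.49 and -0.41 without shNT replicate 2 and shCYP1B1 replicates 1 and 2. For the difference, IGF2BP2 (-0.13 to 0.024) and ABL2 (-0.13 to 0.0093) stood at 0.024 and 0.0093 without RKO control replicate 2, and SMAD3 (-0.078 to 0.021) at 0.021 without shNT replicate 2 and 0.017 without shCYP1B1 replicate 1. None of these had passed with all libraries, and the cause was not tested. Depth limits CYP1B1 in SW480, at 10 to 76 counts per library, and genes near 0 counts in 1 line.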

Other observations

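The heat shock and MondoA tests were chosen after the result was seen, as were the genes named in this part. The split test was chosen before. The glucocorticoid and clock tests were chosen before their own results, but after changes in single genes of these data had been seen. Each list was prompted by genes seen to change and was tested without them, and the camera p-values of these lists are not adjusted over the 4 lists.

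In SW480 with the knockdown of CYP1B1, PER1, a clock repressor gene, rose by a log2 fold change of 2.97 (SE 0.10), the clock output factor gene DBP by 2.58 (SE 0.10) and the repressor gene BHLHE41 by 2.87 (SE 0.16). CRY2, ARNTL and NR1D1 rose by 1.64, 1.22 and 1.00. TXNIP, which encodes an inhibitor of glucose uptake, rose by 4.33 (SE 0.40), from 94.7 and 94.9 CPM with shNT to 1894 and 1920 CPM with shCYP1B1. Its relative ARRDC4 rose by 2.19 (SE 0.17) and the lipolysis inhibitor gene G0S2 by 2.85 (SE 0.25), whereas PFKFB2 fell by 1.15 (SE 0.13).

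In RKO, the ATF4 targets ASNS and TRIB3 stood apart in the 2 overexpression libraries. ASNS, the asparagine synthetase gene, stood at 604 and 213 CPM in overexpression replicates 1 and 2 and at a mean of 938 CPM in the controls, and TRIB3 at 149 and 38.8 CPM against 363. ASNS fell by 1.20 (SE 0.32) and TRIB3 by 1.95 (SE 0.40). ASNS stood at -2.14 and -0.64 without overexpression replicates 1 and 2 and did not pass without RKO control replicate 1 or 2 (adjusted p = 0.0818 and 0.0951), and TRIB3 stood at -3.23 and -1.29 without overexpression replicates 1 and 2. DDIT3, DDIT4, CHAC1 and INHBE, genes of the same stress response, stood at 60.9, 205, 130 and 16.2 CPM in replicate 1 and 11.2, 42.3, 35.6 and 1.41 CPM in replicate 2, with control means of 89.7, 201, 114 and 56.4 CPM.

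The rise of HSPA1A, HSPA1B, DNAJA1 and HSPE1 in RKO led to the hypothesis that heat shock factor 1 targets rose together. Of 22 other targets, 16 rose and 1 fell with overexpression, with a median of 0.51 (camera p = 4.33e-09, and p = 0.0854 with an estimated correlation). HSPA8 rose by 1.33, DNAJB1 by 1.32, HSPH1 by 0.94 and BAG3 by 0.93, and HSPH1 stood at 0.62 without overexpression replicate 2. The medians were 0.37 and 0.53 in overexpression replicates 1 and 2. In SW480, 10 of the targets rose and 0 fell with knockdown (median 0.23, camera p = 0.00495, and p = 0.342 with an estimated correlation; the members were tested with edgeR). A heat shock factor response may therefore have accompanied the manipulation in RKO.

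The rise of PER1 and DBP in SW480 led to the hypothesis that other clock genes moved together. The 16 others tested include core clock genes, and BHLHE41, CRY2, ARNTL and NR1D1, named above, are among them. Of these 16, 7 rose and 1 fell, while 50.6% of all genes tested were called in SW480. The list's median was 0.56 (camera p = 0.00333, and p = 0.0346 with an estimated correlation), and 0.46 and 0.47 in the shCYP1B1 libraries. In RKO, 0 of the 16 rose and 6 fell by edgeR (camera p = 0.0875, and p = 0.141 with an estimated correlation). A shift of clock genes may have come with the knockdown, but the list was prompted by related genes of the same libraries and is not independent support. A difference in the time of harvest between the cultures stays open, although ARNTL, known to cycle out of phase with PER1 and DBP, rose with them.

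A rise of HSD11B1, whose enzyme makes active glucocorticoid, led to a test of 21 glucocorticoid receptor targets other than PER1 in SW480. Of these, 9 rose and 2 fell, with a median of 0.56 (camera p = 0.0555, and p = 0.320 with an estimated correlation). MT1X, BCL6 and TSC22D3 rose by 1.48, 1.34 and 1.78, while the 2 that fell, NFKBIA and SCNN1A, stood at -0.81 and -0.95. SGK1, FKBP5 and DUSP1 stood at -0.55, -0.18 and 0.08 and did not pass. The test leaves the hypothesis open. For the glucose-sensing factors MondoA and ChREBP, 6 of 13 targets other than TXNIP and G0S2 rose and 3 fell in SW480, with a median of 0.030 (camera p = 0.486, and p = 0.634 with an estimated correlation), which leaves that open too. In RKO, 1 of these targets rose and 6 fell (median -0.27, camera p = 0.0108, and p = 0.132 with an estimated correlation).

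Of the 34 splits of the 8 libraries into 4 and 4 that could be fitted with cell line as a covariate, 2 gave at least as many genes as the 1140 that followed CYP1B1, the real split included. The other of these gave 2332 genes and set RKO control and SW480 shNT against the manipulated libraries of both lines, which is a contrast of the design. It was not fitted without overexpression replicate 1, so a response shared by both manipulated cultures stays open. Each of the remaining splits gave 85 genes or fewer, but they set libraries of the same group on opposite sides. Low counts there follow from any difference between groups, so they do not speak for genes following CYP1B1. The share of splits does not exclude chance.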
